A study of Mus musculus with 7 samples.

How the data were processed

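Gene expression was measured on 7 single-channel Affymetrix arrays hybridised with biotin-labelled cDNA from hematopoietic stem cells (HSCs) of mouse bone marrow. Per the labels' protocols, marrow was taken from mice aged 8 weeks and depleted of lineage-positive cells. The stem cells were then isolated by SLAM-family surface markers, total RNA was extracted with a small-scale column kit, and biotinylated cDNA was prepared from it with a Nugen WT-Ovation kit. The labels placed 3 arrays in the Ahr knockout group (Ahr-KO) and 4 in the wild-type group (WT), both on a C57BL/6J background. They do not say whether each array came from a separate mouse or pool of mice, so p-values measure only the spread between these arrays, which may be technical.

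The deposited table holds 1 intensity per probe set and array on a linear scale, never negative. Affymetrix Expression Console is named in the submitters' processing notes. The summarization algorithm, its version, the background correction and the normalization are not given in the sources used here. The deposited intensities had different medians on the arrays (16.9 to 22.1), so they were not forced to 1 distribution. Between 800 and 1621 of the 41155 probe sets per array were listed at exactly 0. For arrays there is no read depth: the number of arrays limits the precision. No detection call accompanies the intensities, so the 95th percentile of 1108 olfactory receptor probe sets on each array (33.8 to 42.8) served as a background mark. That mark was chosen after the data were seen.

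Probe sets were paired with genes through the platform annotation. It listed 25335 of the 41155 rows, of which 23521 had 1 gene symbol and 1814 had several. The other 15820 rows were unnamed here and were left out of the main test. Of the rows with 1 symbol, 23328 matched the GRCm38.p6 RefSeq gene table by Entrez ID, which supplied current symbols and the neighbours of Ahr. The genome build behind the array is not given in the sources used here, so no coordinates are printed.

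Intensities were transformed as log2(intensity + 1), the pseudocount fixed in advance for linear values. Differences are Ahr-KO minus WT on that scale, which understates the fold change of dim genes. The comparison was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 7 arrays with genotype as the only term. P-values were two-sided and adjusted by Benjamini-Hochberg over the 25335 probe sets, with a threshold of 0.05. Adjusted p-values without another name come from this fit, and unadjusted p-values from the same moderated test. Standard errors (SE) are moderated too, with each variance drawn toward a value shared by all probe sets. They can exceed the own spread of the steadiest probe sets.

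For gene lists, each gene was represented by its probe set with 1 symbol and the highest mean over all 7 arrays, chosen without regard to genotype, which gave 22180 genes. Of these genes, 1082 had more than 1 such probe set. The lists, 17 of pathways or functions and 9 of cell type markers, were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 26 lists. They held 376 entries, of which 331 were measured; the rest had no probe set with 1 symbol under their name. No measured gene stood in more than 1 list. Genes near Ahr, within 20 Mb in the RefSeq table, were compared with other genes by Fisher's exact test.

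The lists, the tests and the rule for named genes were fixed before the data were examined. The rule named Ahr, then for each direction up to 12 probe sets with 1 symbol whose 3 Ahr-KO values did not overlap the 4 WT values. Those past the adjusted threshold came first by size of the difference. Because none passed, the places were filled by smallest unadjusted p among probe sets whose higher group mean reached the median of all tested probe sets. Predicted genes were counted but not named. Up to 4 members of each list with the smallest unadjusted p were also eligible. Genes named outside this rule are marked as such.

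The alternatives were leaving out each array, the replicate number as a block, quantile normalization, median centring, filters on dim probe sets, array weights, a trended or robust variance prior, a pseudocount of 16, other sets of rows, other thresholds, an unmoderated test, other set tests, and another window around Ahr. The procedure was tested on simulated arrays with the real means and within-group spread of the 25335 probe sets. Of 200 seeded changes of 16-fold, 46.5% were recovered at adjusted p under 0.05, and 75.5% of those of 64-fold. None of the 2-fold or 4-fold changes was recovered. A simulated shift of 1 log2 unit in the cell cycle, HSC identity or AhR target list gave camera adjusted p-values of 1.36e-07, 4.26e-06 and 0.00646 among the 26 lists. Genes were simulated independently. In the real arrays, median pairwise correlations within genotype were 0.236, 0.126 and 0.0757 for these lists. The simulation therefore overstates how readily a shift would be found in lists whose members vary together.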

Results

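Expression was profiled in hematopoietic stem cells, the rare bone marrow cells that maintain all blood lineages, to ask how loss of the aryl hydrocarbon receptor (AhR) gene affects their transcripts. AhR is a ligand-activated transcription factor that binds environmental and endogenous aromatic compounds. Cells came from 8-week-old Ahr-KO and wild-type mice, with 3 and 4 arrays. Median intensity was 16.9, 20.3 and 18.5 on the Ahr-KO arrays and 19.4, 16.95, 19.9 and 22.1 on the WT arrays. Pairwise correlations of log2 intensities across probe sets, which are not independent replicates, ran from 0.619 to 0.772, with a median of 0.679 among Ahr-KO arrays, 0.657 among WT arrays and 0.676 between the genotypes. Of the 25335 probe sets tested, 3643 lay above the olfactory receptor background on all 7 arrays, 8590 on none and 13102 on 1 to 6. By array, the share above it was 34.9, 41.9 and 36.2% in Ahr-KO and 36.4, 30.7, 34 and 44.9% in WT. WT replicate 2, with the smallest share, also had the lowest mean correlation with the other arrays (0.625).

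The intensity of Ahr (probe set 17280729) was not lower on the arrays labelled Ahr-KO. It was 65.7 ± 61.6 (SD, n = 3) in Ahr-KO and 31.1 ± 19.1 (SD, n = 4) in WT. The single values were 34.1, 137 and 26.4 in Ahr-KO against 31.3, 57.9, 14.9 and 20.5 in WT. The log2 difference was 0.84 ± 0.73 (SE; limma adjusted p = 0.963), or 0.13 without Ahr-KO replicate 2. An exact permutation test of the means gave a two-sided p of 0.314, where the smallest p the 35 splits allow is 0.0286. Ahr exceeded the olfactory receptor background on 1 Ahr-KO array and 1 WT array. The labels do not say which part of the gene was deleted or which part the probe set covers, so this measurement does not check the genotype labels, and Ahr-KO names the label throughout.

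No probe set differed between genotypes at an adjusted p under 0.05 by limma, and the lowest adjusted p was 0.961. At an unadjusted p under 0.05 there were 1067 probe sets, 505 with higher and 562 with lower values in Ahr-KO, where 1267 of 25335 would be expected by chance. This split had no stable direction: 47.3% were higher, against 56.6% after median centring, 53.7% after quantile normalization and 37.5 to 61.8% when single arrays were left out. The unmoderated test also gave 0 at adjusted p under 0.05 and 1094 unadjusted. Ahr-KO and WT values did not overlap for 1454 probe sets, or 5.74%, where chance gives 5.71%. The median standard error of a log2 difference was 0.687. Residual spread depended on level: the median residual SD was 0.215 log2 units in the brightest 1% of probe sets, and 1.19 between the 75th and 90th percentiles of mean level.

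Among probe sets meeting the naming rule's conditions on overlap and level, those with the smallest unadjusted p and higher values in Ahr-KO included 11 named genes. None of these genes passed the adjusted threshold. Cdca5, which encodes the sister chromatid cohesion factor sororin, had an intensity of 376 ± 61.0 (SD, n = 3) in Ahr-KO and 14.2 ± 18.8 (SD, n = 4) in WT, a log2 difference of 5.40 ± 0.90 (SE). Gpr182, a G-protein-coupled receptor gene, stood at 761 ± 171 (SD, n = 3) against 42.6 ± 39.8 (SD, n = 4). The chemokine gene Cxcl9, known to be induced by interferon gamma, stood at 376 ± 117 (SD, n = 3) against 46.6 ± 14.1 (SD, n = 4). Cpt1a, whose product admits long-chain fatty acids to mitochondria, stood at 183 ± 88.4 (SD, n = 3) against 17.3 ± 8.57 (SD, n = 4). The cap-binding complex gene Ncbp2 differed by 3.14 log2 units and Cnot10, of the CCR4-NOT deadenylase complex, by 4.46. For Cnot10 the Ahr-KO values were 926, 960 and 7468. The remaining genes were Slc41a3, Rgs4, a regulator of G-protein signalling, Rassf2, Prepl and Plekhg3, with log2 differences of 3.47, 3.06, 2.96, 2.98 and 3.10. The limma adjusted p was 0.961 for each of these 11 genes, which the rule had ranked by unadjusted p. All 11 exceeded the olfactory receptor background on every Ahr-KO array, and 5 of them exceeded it on no WT array. The sizes of such differences depend on the pseudocount: with 16 in place of 1, Cdca5 differed by 3.86, and Prepl and Plekhg3 by 1.95 each.

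Among probe sets meeting the same conditions, those with the smallest unadjusted p and lower values in Ahr-KO included 9 named genes, also with an adjusted p of 0.961 each. A probe set of Col1a2, a chain of fibrillar type I collagen, was listed at 0, 5.86 and 1.95 in Ahr-KO and stood at 47.2, 398, 186 and 341 in WT, a log2 difference of -6.10 ± 0.93 (SE), and -3.50 with a pseudocount of 16. The other Col1a2 probe set did not share this size: its log2 difference was -0.60 ± 0.56 (SE; limma adjusted p = 0.963). Etfdh, which passes electrons from fatty acid and amino acid oxidation to ubiquinone, stood at 11.6 ± 7.17 (SD, n = 3) in Ahr-KO and 227 ± 178 (SD, n = 4) in WT. The phosphoinositide phosphatase gene Mtmr3 stood at 26.8 ± 22.5 (SD, n = 3) against 260 ± 119 (SD, n = 4). The endoplasmic reticulum gene Reep3 differed by -2.28 log2 units and the nuclease gene Dnase1 by -2.11. The zinc finger genes Zfp141, Zfp715 and Zfp652 differed by -3.36, -3.79 and -2.77; they belong to a large family, and probes shared with related genes were not checked. The microRNA gene Mir1955 stood at 0.01, 0.9 and 2.47 in Ahr-KO, below background, and at 20.6, 446, 88.6 and 41.5 in WT. Of these 9 genes, 7 exceeded the olfactory receptor background on every WT array. Dnase1 exceeded it on WT replicate 1 alone, and Mir1955 on every WT array except replicate 1. On the Ahr-KO arrays 8 of the 9 genes exceeded it on none, so the sizes of their differences depend on the pseudocount. Another 4 of the 24 probe sets chosen by rule belonged to predicted genes.

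**Figure D1:**
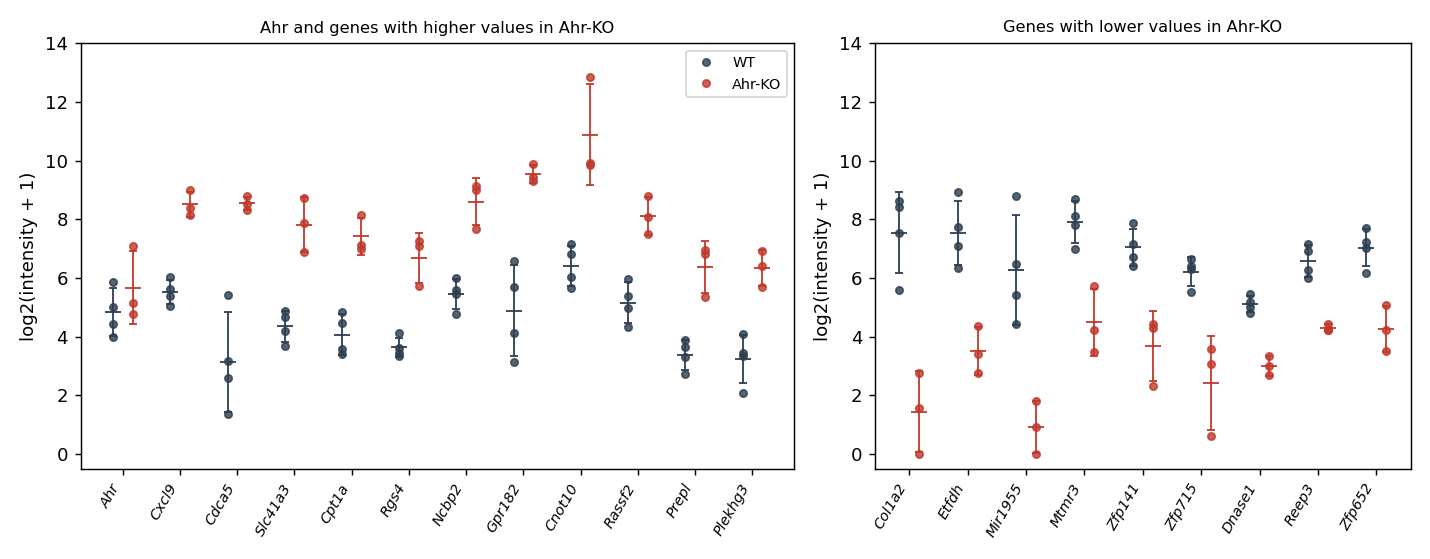
Each point is 1 array's log2(intensity + 1) for Ahr and the genes chosen by rule, in WT (dark, n = 4) and Ahr-KO (red, n = 3), with horizontal marks at the group mean and bars of 1 SD. Ahr values overlap between genotypes; the values of the other genes do not overlap because the rule required it, and none passed the adjusted threshold.

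AhR target genes, such as the xenobiotic-metabolising cytochromes P450, gave little signal on either genotype on the probe sets chosen for the list. Of 8 measured targets, 3 exceeded the olfactory receptor background on no array, 4 on 1 or 2 arrays, and 1 on all 7, so a difference in most of them was not detectable here. Values were higher in Ahr-KO for 4 and lower for 4, and none of these 8 probe sets had an unadjusted p under 0.05. Cyp1b1, above background on no array, differed by 0.75 ± 0.46 (SE) and Cyp1a2 by -0.73 ± 0.55 (SE), or -0.43 without Ahr-KO replicate 3 and nearly the same without WT replicate 2. Nqo1, a quinone reductase, differed by -1.25 ± 1.02 (SE), and by -0.50 without WT replicate 4. Tiparp, a feedback repressor of AhR, differed by 0.60 ± 0.60 (SE), or 0.20 without WT replicate 3 and 0.40 without Ahr-KO replicate 3. Its other probe set, dimmer in mean log2 intensity, differed by 3.72 ± 0.93 (SE, limma adjusted p = 0.963) and was under 0.05 unadjusted. That probe set stood at 101, 22.5 and 48.7 in Ahr-KO and at 2.3, 3.02, 0.02 and 13.6 in WT. The WT values lay below the olfactory receptor background, so the size of the difference depends on the pseudocount. With a pseudocount of 16, where the probe set of highest mean was chosen anew, Tiparp passed when adjusted over the list alone. The list median was 0.08, its mean -0.06, and the camera direction was upward with an adjusted p of 0.891. Among 10 AhR complex and partner genes, 6 were higher (list camera adjusted p = 0.341). The coactivator gene Ncoa3, above background on no WT array, differed by 3.30 ± 0.94 (SE), or 2.14 with a pseudocount of 16. Its limma p adjusted over the list alone was 0.0829. The chaperone gene Hsp90aa1 differed by -0.39 ± 0.40 (moderated SE, limma adjusted p = 0.963). Its values did not overlap between genotypes, and its log2 SDs were 0.15 in Ahr-KO and 0.09 in WT.

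Stem cell programmes likewise gave no list past the threshold. Of 17 HSC identity genes, 11 had lower values in Ahr-KO (camera adjusted p = 0.622). Their mean log2 level was 5.31 on WT replicate 2, the array with the fewest probe sets above background, and 6.94, 7.51 and 7.86 on the other WT arrays. Without WT replicate 2 the camera adjusted p of these genes was 0.0764. Slamf1, the CD150 marker used to define these cells, went the other way, with a difference of 2.58 ± 0.97 (SE; limma adjusted p = 0.963), while the transcription factor genes Gata2 and Hlf differed by -2.11 (-1.31 without WT replicate 3) and -0.66. Of 16 quiescence genes, 10 were higher (camera adjusted p = 0.341). Among them were the nuclear receptor genes Nr4a1, at 1.61 (0.88 without Ahr-KO replicate 3), and Nr4a2, above background on no WT array, at 1.76. Foxo1 differed by -0.85. Without Ahr-KO replicate 1, Nr4a2 differed by 1.0 and Foxo1 by -0.50. The 32 cell cycle genes divided into 15 higher and 17 lower, with a median of -0.06 and a camera adjusted p of 0.891. Their mean log2 level was 7.85 on Ahr-KO replicate 2 and 5.82 and 6.47 on the other Ahr-KO arrays; without that replicate the list was lower with an adjusted p of 0.116. Plk1, at 2.62, rested on the same array (919 against 16.9 and 21.9) and was 0.78 without it. Mcm4 differed by -1.94, and by -0.78 without Ahr-KO replicate 3, and Top2a by -1.26. Of 13 HSC ageing genes, 9 were lower (adjusted p = 0.891), with Clu at 0.60, or 0.39 without Ahr-KO replicate 1; Ehd3 was lower but exceeded the olfactory receptor background on no Ahr-KO array. Of 17 genes chosen for their links to myeloid neoplasms, 10 were lower (adjusted p = 0.891), with Jak2 at -1.03 and Calr at 0.74, or -0.50 and 0.47 without Ahr-KO replicate 1.

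Mtor, the growth-control kinase, was the list member that passed when adjusted over the list alone with all 7 arrays. Its log2 value was 6.96 ± 0.37 (SD, n = 3) in Ahr-KO and 5.03 ± 0.43 (SD, n = 4) in WT. The difference was 1.93 ± 0.46 (SE), with a limma p of 0.0386 adjusted over the list alone and 0.963 over all probe sets. Adjusted over the list alone, the p was 0.0453 without WT replicate 1. Without any other single array it missed the threshold, at 0.127, 0.0717 and 0.17 without Ahr-KO replicates 1, 2 and 3, and 0.0788, 0.109 and 0.12 without WT replicates 2, 3 and 4. Other members passed in its place in some of these fits: Sod2, Car1, Car2 and Cxcl12 without Ahr-KO replicate 2, and none without WT replicate 4. Of the 12 measured PI3K and mTOR genes, 8 were lower; the list median was -0.47 and its mean 0.01. The camera direction was upward, and downward after quantile normalization or without WT replicate 2, with an adjusted p of 0.891. Of 14 Notch, Wnt and Hedgehog genes, 8 were higher (adjusted p = 0.891). Hes1, a Notch effector, differed by 3.59 ± 1.09 (SE), and the receptor gene Notch2 by -2.21 ± 0.87 (SE), each with a limma adjusted p of 0.963. With a pseudocount of 16, Hes1 differed by 2.37 and Notch2, above background on no Ahr-KO array, by -1.26.

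Of 16 oxidative phosphorylation genes, 14 had higher values in Ahr-KO. Uqcrc1, of respiratory complex III, stood at a log2 value of 8.56 ± 0.06 (SD, n = 3) against 6.70 ± 0.74 (SD, n = 4), and Ndufb5 and Sdha differed by 0.98 and 1.18. The mean log2 level of the list was 7.71 on WT replicate 2 and 8.91, 8.45 and 8.96 on the other WT arrays; without that replicate, Ndufb5 differed by 0.49 and Sdha by 0.21, and the camera adjusted p was 0.234. With all arrays the list missed the threshold, with a camera adjusted p of 0.112, and 0.858 with an estimated correlation. Of 13 glycolysis and hypoxia genes, 9 were higher (adjusted p = 0.465), Ldha by 1.09, or 0.71 without Ahr-KO replicate 1. The 12 oxidative stress genes had a median of 0.22, a mean of -0.12 and an upward camera direction that turned downward after quantile normalization and without Ahr-KO replicate 2, WT replicate 2 or WT replicate 3 (adjusted p = 0.891), with the mitochondrial dismutase gene Sod2 at -2.66 ± 1.04 (SE), or -1.63 without Ahr-KO replicate 1. Of 13 NF-kB and inflammatory genes, 9 were higher (adjusted p = 0.341). The chemokine gene Ccl3 differed by 3.12 ± 1.33 (SE), or 1.81 without WT replicate 1, where it was listed at 0.04, and the cytokine gene Il1b, above background on no Ahr-KO array, by -1.34 ± 0.50 (SE), or -0.84 with a pseudocount of 16. The 16 interferon response genes divided into 8 and 8 (adjusted p = 0.622), with Irf7 at 3.33 ± 1.49 (SE). The 13 p53 and DNA damage genes had a median of 0.07, a mean of -0.07 and a downward camera direction (adjusted p = 0.741). Trp53inp1 was lower but exceeded the olfactory receptor background on no Ahr-KO array and 1 WT array. The immediate early and heat shock genes, in part a sign of cell handling, had a median of 0.15 (adjusted p = 0.746), with Fos at 1.05 (0.52 without Ahr-KO replicate 1). The ribosomal protein genes had a median of 0.12 (adjusted p = 0.639), with Rpl19 at 0.24.

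Granulocyte and basophil markers, which the lineage depletion and sort should leave low, included abundant transcripts that were uneven between arrays. Of 14 granulocyte and monocyte markers, 12 had higher values in Ahr-KO, with a mean log2 level of 7.88 ± 0.91 (SD, n = 3) against 7.04 ± 1.67 (SD, n = 4). The granule protease genes Prtn3 and Ctsg differed by 1.34 and 1.27 (Ctsg by 0.73 without WT replicate 1), and the Fc receptor gene Fcgr3 by 1.80 ± 0.58 (SE). The list had a camera adjusted p of 0.112, and an adjusted p of 0.858 with an estimated correlation. It depended on single arrays. The camera adjusted p was 0.494 without Ahr-KO replicate 2, 0.602 without WT replicate 1 and 0.348 without WT replicate 4. Without WT replicate 2 the camera adjusted p was 0.000361. The mean log2 level of the list was 8.85 on that array and 4.88, 7.63 and 6.79 on the other WT arrays. Leaving out the highest WT array raises the difference between genotypes. Of 7 mast cell and basophil markers, 5 were higher (adjusted p = 0.444). The basophil protease gene Mcpt8 stood at 1176, 1691 and 348 in Ahr-KO and at 3.76, 773, 1352 and 664 in WT.

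**Figure D2:**
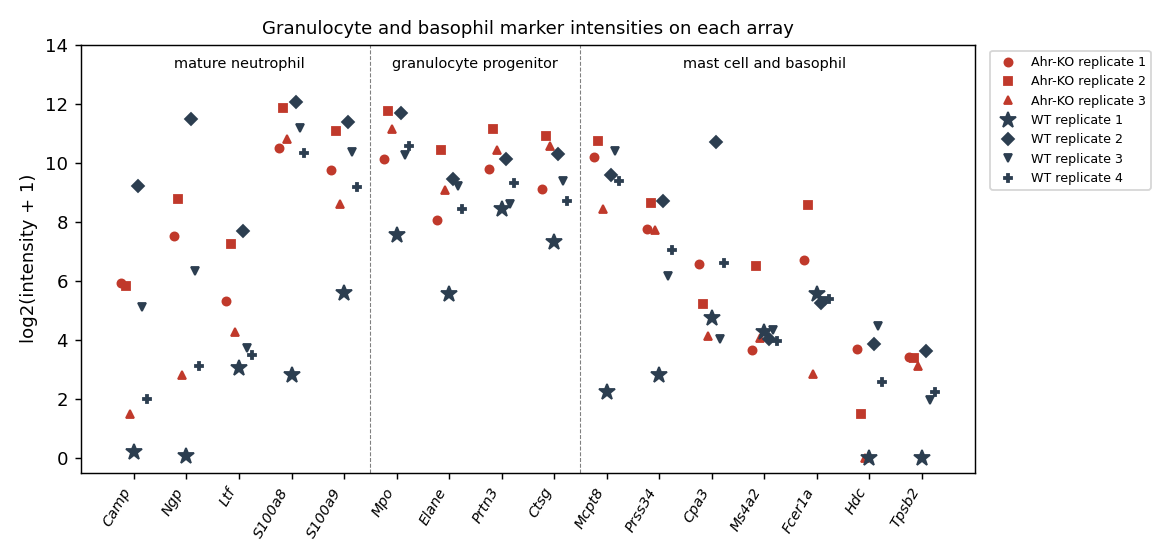
Each symbol is 1 array's log2(intensity + 1) for neutrophil, granulocyte progenitor, and mast cell and basophil marker genes (Ahr-KO red, n = 3; WT dark, n = 4). WT replicate 1 (stars) has the lowest S100a8, Mpo and Mcpt8 values of the 7 arrays, with Mcpt8 at 3.76 against 348 to 1691 on the others. S100a8 and Mpo are named outside the rule.

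Of 10 T and NK cell markers, 8 were higher (camera adjusted p = 0.112, and 0.0427 without WT replicate 2). The mean log2 level of that list was 4.74 on WT replicate 2, the highest of the WT arrays, and 4.27, 4.6 and 4.12 on the others. With an estimated correlation the adjusted p of that list was 0.858, and 6 of the 10 markers exceeded the olfactory receptor background on no array. Nkg7 differed by 1.34; Klrd1, at 2.21, rested on Ahr-KO replicate 2 (180 against 3.54 and 9.40) and was 0.64 without it. The 8 B lymphoid markers, 4 of which exceeded the background on no array, had lower values in Ahr-KO, with a list median of -0.18 (adjusted p = 0.496), with Pax5 at -0.87 (-0.42 without Ahr-KO replicate 1), above the background on 1 array; Ebf1, at -0.20, was above 0 when Ahr-KO replicate 2 or WT replicate 3 was left out. Of 10 macrophage and dendritic markers, 8 were lower (adjusted p = 0.16), with the class II gene H2-Eb1 at -2.30 ± 0.76 (SE). The erythroid list had a median of -0.23 (adjusted p = 0.678). Its member Car2, a carbonic anhydrase gene, stood at a log2 value of 8.72 ± 0.46 (SD, n = 3) against 10.2 ± 0.22 (SD, n = 4), with a limma p of 0.0805 adjusted over the list alone. The megakaryocyte and platelet list had a median of -0.01, a mean of 0.02 and a downward camera direction (adjusted p = 0.891), with Gp9 at -1.55. The multipotent and lymphoid-primed progenitor list had a median of 0.46 (adjusted p = 0.341); its member Ccr9 was higher in Ahr-KO but exceeded the olfactory receptor background on no array. The stroma and endothelium list had a median of -0.84 (adjusted p = 0.813), with the endothelial cadherin gene Cdh5 at 2.40 (1.54 without Ahr-KO replicate 2) and the pericyte receptor gene Pdgfrb lower, above the background on no Ahr-KO array and 1 WT array. With an estimated correlation, no list passed, and adjusted p-values ran from 0.858 to 0.9. Over all lists, 0 of 331 members passed over all probe sets, 1 when adjusted over the list alone (0 without WT replicate 4, 4 without Ahr-KO replicate 2 and 6 with a pseudocount of 16), 18 had an unadjusted p under 0.05, and 24 had values that did not overlap. The camera direction turned when 1 array was left out for 8 lists: cell cycle, myeloid neoplasm, Notch, immediate early, HSC ageing, oxidative stress, PI3K and mTOR, and megakaryocyte.

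**Figure D3:**
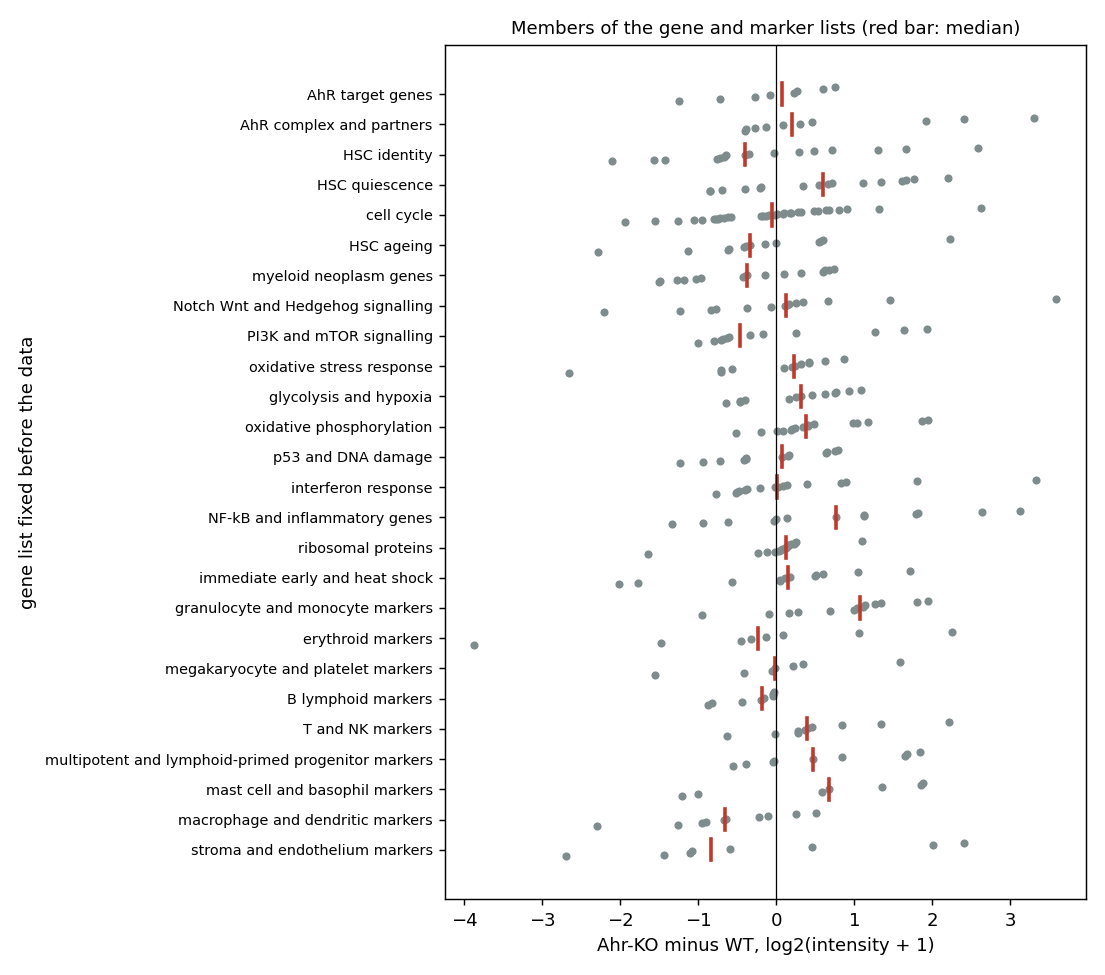
Each grey point is 1 gene's Ahr-KO minus WT difference in log2(intensity + 1), with genes grouped in rows by the 26 lists fixed before the data, and the red bar is the list's median. List medians lie between -0.84 and 1.07, and no list passed camera's adjusted threshold.

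Because a targeted allele can be inherited together with its neighbours, genes within 20 Mb of Ahr were compared with the other placed genes. Of 152 neighbours, 9 had an unadjusted p under 0.05, or 5.92%, against 877 of 21800 elsewhere, or 4.02%. The odds ratio was 1.5 (95% interval 0.672 to 2.95; two-sided Fisher's exact p = 0.214). The neighbour with the smallest p was Baz1a, a chromatin remodelling gene, at 2.98 ± 0.71 (SE). Colec11, a collectin gene, came next at -2.47 ± 0.70 (SE). Both were chosen after their values were seen. Baz1a exceeded the olfactory receptor background on no WT array and Colec11 on no Ahr-KO array. With a pseudocount of 16 these genes differed by 1.86 and -1.18. The odds ratio was 1.85 (p = 0.0468, Fisher's exact test) without WT replicate 4 and 0.933 without Ahr-KO replicate 3. With a pseudocount of 16 it was 2.26 (p = 0.0102, Fisher's exact test). Fisher's test treats genes as independent, although all were measured on the same 7 arrays. At that pseudocount, 3 of the 35 splits of the arrays, the real one included, gave an odds ratio as large.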

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

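Of the tests in this part, the one on overall array brightness was chosen after the result was seen, and the one on neutrophil genes outside the lists was added after the pattern was seen. Within the 4 WT arrays, 154 values were screened for 1 array standing apart from the rest by Dixon's ratio, on the log2 scale for intensities, and 7 did, where about 7.7 are expected by chance. Mcpt8, a basophil protease gene, was listed at 3.76 on WT replicate 1 and at 664 to 1352 on the other WT arrays. Ccl3, a chemokine gene, stood at 0.04 on the same array against 29.1 to 48.1, and Sod2, a mitochondrial dismutase gene, at 345.7 against 80.3 to 89.5. On WT replicate 2, Sdha, a succinate dehydrogenase gene, stood at 16.62 against 222 to 293, the chaperone gene Hsph1 at 35.14 against 96.1 to 108, and Plscr2 at 22.34 against 45.3 to 51.2. On WT replicate 3, Gclm, of glutathione synthesis, stood at 75.94 against 253 to 298.

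Other granulocyte markers, named here outside the rule, were also low on WT replicate 1. S100a8, an abundant neutrophil transcript, stood at 5.97 there and at 1298 to 4237 on the other WT arrays. Mpo, which progenitor cells can also express, stood at 186 against 1217 to 3284. WT replicate 1 was not the only array apart. Camp and Ngp stood at 590 and 2837 on WT replicate 2. They were low on WT replicate 1 (0.16 and 0.04), WT replicate 4 (2.98 and 7.73) and Ahr-KO replicate 3 (1.78 and 6.09), and between these on the remaining arrays. The differences of WT replicate 1 given below are from a mean that includes WT replicate 2. A dimmer array is argued against in the deposited intensities only. There the median difference of WT replicate 1 from the other WT arrays over all tested probe sets was 0.0141 log2 units. Because the normalization is not given, this cannot show whether the array was dimmer before processing. The medians over 5 mature neutrophil genes (-5.23), 4 granulocyte progenitor genes (-2.72) and 7 mast cell and basophil markers (-2.61) describe the lists that drew attention to the array and test nothing further, so basophil content stays open. Of 8 other neutrophil genes outside every list and outside the naming rule, 6 exceeded the olfactory receptor background on at least 3 arrays. Their median was -2.94, at percentile 0.01 of 10000 random lists matched on level. Lcn2 stood at -3.81 and Pglyrp1 at -3.95, but Mmp9, above background on all 7 arrays, at -0.47 and Chil3 at 0.81. The random genes did not have to exceed the background. The granulocyte and monocyte list also varied together (median pairwise correlation 0.594), so the percentile can overstate how unusual the array is. A candidate explanation is that arrays differ in neutrophil transcripts, from cells or free RNA carried through a sort whose lineage depletion should remove them; Lcn2 was also low on WT replicate 4 (11.5) and Ahr-KO replicate 3 (7.47), and a difference between genotypes stays open.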

How the results depend on the processing

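The filter on the olfactory receptor background was chosen after seeing the data; the other settings were planned. The count of probe sets past the adjusted threshold was 0 under every setting run, including an adjusted threshold of 0.1. The 1067 probe sets with an unadjusted p under 0.05 became 661 without the dimmest 40%, 495 above the olfactory receptor background and 1781 over all 41155 rows, because the number of rows tested differed, and lay between 954 and 1339 when single arrays were left out. The percentage of them higher in Ahr-KO was 47.3, 56.6 after median centring, 53.7 after quantile normalization, and 37.5 to 61.8 over the arrays left out, so the split has no stable direction. No list passed in the main test. With array weights 1 list passed, granulocyte and monocyte markers. Over the arrays left out 0 to 2 lists passed, the 2 being that list and the T and NK markers without WT replicate 2. In both lists WT replicate 2 had the highest mean level of the WT arrays. The cause was not tested. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.858. The odds ratio for neighbours of Ahr passed the threshold at 2.26 with a pseudocount of 16 and at 2.46 (Fisher's exact p = 0.0323) above the olfactory receptor background. It also passed at 1.85 (Fisher's exact p = 0.0468) without WT replicate 4. Over the arrays left out it ran from 0.933 to 1.85, and the cause was not tested. The Ahr difference stayed above 0, between 0.127 and 1.29 over the arrays left out, and was 0.63 with a pseudocount of 16. Among 317 refitted values of the 20 named genes none passed; their sign tests nothing when an array is left out, since they were chosen for values that do not overlap. Among 1616 of list members 9 changed sign. Adjusted over the list alone, the p of Mtor ran from 0.00864 with a pseudocount of 16 to 0.373 with a replicate block, and 0 to 6 list members passed, not always the same ones. Over the arrays left out, the differences ran from -0.0112 to 2.55 for Deptor, -0.0543 to 2.75 for Dntt, -0.385 to 0.0333 for Ebf1, -3.09 to 0.0478 for Ier3, -0.000164 to 2.72 for Mcpt8, -0.301 to 1.12 for Ms4a2, -0.212 to 2.83 for Ppbp and -0.666 to 0.0256 for Vpreb1. With a replicate block, 0 probe sets passed, 1120 had an unadjusted p under 0.05, 65.7% of these were higher, and the odds ratio near Ahr was 1.05 (Fisher's exact p = 0.842). Same-numbered arrays did not deviate together (r = 0.0227, -0.0646 and 0.0101), so the numbers were not taken as pairs. Signal over background limits what can be seen: 8590 of 25335 probe sets exceeded the olfactory receptor background on no array.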

Other observations

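The tests in this part were written before their results were seen, except the choice of the genes in this paragraph. Some genes of stem and progenitor cells exceeded the olfactory receptor background on all 7 arrays: Kit, the stem cell factor receptor, ranged from 653 to 1258, and the transcription regulators Hlf from 310 to 900 and Mllt3 from 484 to 989. Others did not. Mecom was listed at 0 on WT replicate 2 and ranged from 54.2 to 675 elsewhere. Slamf1 exceeded the olfactory receptor background on 3 of 3 Ahr-KO arrays and 1 of 4 WT arrays. Cd48, whose protein the SLAM gate excludes, ranged from 11.5 to 679 and exceeded that background on 5 of 7 arrays. Xist stood at 829 to 1763, and the Y-linked genes Kdm5d, Uty and Eif2s3y exceeded the background on none, so all 7 arrays showed a female pattern.

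For unadjusted p under 0.05, 20 of the 35 splits of the 7 arrays into 3 and 4, the real one included, gave as many probe sets as the real 1067, with 1728 the highest other, so chance is not excluded for that count. The counts past the adjusted threshold were 0 for probe sets and for gene lists. Against a count of 0, 35 of 35 splits must give as many, so these comparisons test nothing; the highest count of another split was 4 for probe sets and, in a different split, 5 for lists.

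The spread that hides single genes was in part shared between genes. Random loss and gain of transcripts during amplification of little RNA may add to it. As the whole source of spread in the cell cycle genes, such loss and gain is argued against by the cell cycle list. The median pairwise correlation of its 32 genes within genotype was 0.236, at percentile 100 of 1000 random lists matched on level. The granulocyte and monocyte list had 0.594, the interferon list 0.262, and the mast cell and basophil list 0.353. Of the 26 lists, 7 reached the 95th percentile of their random lists and the rest did not, with HSC quiescence at percentile 1.9. The mean log2 level of the cell cycle list was 5.82, 7.85 and 6.47 on the Ahr-KO arrays. On the WT arrays it was 7.02, 6.41, 6.97 and 6.85. The correlation of that list, and the argument from it, therefore rest mainly on the Ahr-KO arrays. How much of the remaining spread is random loss, sort purity or differences between mice stays open.

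Neighbours of Ahr are a hypothesis to follow. The pseudocount of 16 gave the smallest Fisher's exact p of the settings run (0.0102). The windows and splits below were run at that setting alone, and many windows overlap. Both comparisons therefore lean toward an excess. With a pseudocount of 16, 13 of 152 genes within 20 Mb had an unadjusted p under 0.05, or 8.55%, against 3.97% elsewhere. Among these, Baz1a, Hpcal1, Id2, Cog5 and Cpsf3 had higher and Ifrd1, Colec11 and a predicted gene lower values in Ahr-KO, without overlap between genotypes; they were chosen after their values were seen. The odds ratio lay at percentile 99.9 of 1971 windows of the same width around other genes, which describes the same excess and does not test its source. Sequence of another strain kept around the targeted allele may be one source, and was not tested separately. Chance is not excluded, since 3 of the 35 splits gave an odds ratio as large as 2.26, the highest other being 2.41. The strain in which the allele was made is not given in the labels, and with a pseudocount of 1, which gives dim genes more weight, the odds ratio was 1.5, or 1.55 (Fisher's exact p = 0.387) within 10 Mb.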
